A study of Drosophila melanogaster with 4 samples.

How the data were processed

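Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H4 acetylated at lysine 16 (H4K16ac) in larvae of the third instar of the wild-type Oregon-R strain of Drosophila melanogaster. The series holds 2 ChIP replicates made with a rabbit polyclonal antibody to H4K16ac and 2 libraries that the labels call input DNA. Per the labels' protocols, the chromatin was crosslinked with formaldehyde and sheared by sonication. Groups and replicate numbers were taken from the sample titles. The titles call the ChIP samples replicates and do not say whether they came from separate larval collections, so the spread between them may be partly technical.

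Each region in the deposited files has a start position, an end position and a score. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The coordinates are on FlyBase r5, per the file headers, which also give the length of every sequence. Each ChIP replicate has its own list of significantly enriched regions, and 1 combined list covers the replicate set as a whole. The authors' region caller, its thresholds, the use made of the input libraries and the way the combined list was built are not given in the sources used here. The replicate lists hold 4070 and 4164 regions and the combined list holds 5252. No region is shorter than 1301 bp in either replicate list or than 1001 bp in the combined list. Regions within a list do not overlap. In each list 1 region runs past the sequence length in the header and was clipped there for all measures of coverage.

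The score per region was deposited by the authors with no unit. Its scale was examined in the values. Relative to the most common score of each list, the scores of regions under 10 kb were read as powers of 2, and 100% in replicate 1, 100% in replicate 2 and 99.98% in the combined list then equalled a ratio of whole numbers with a denominator of at most 3000, within a relative tolerance of 1e-12. Read as powers of e or of 10, at most 0.081% did so. Scores were therefore treated as log2 values, in which a difference of 1 is a doubling of the underlying ratio. Which quantities form the ratio is not given. X and autosomes are compared by the authors' scores only within a list. Means and SDs of scores over the replicates, and scores of the combined list beside them, may also reflect the scale of each list. The files give no read counts per library, so the depth is unknown and no counting intervals were set.

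Coverage was computed as the percentage of bases of a sequence that lie in an enriched region. The main contrast set X against the 4 large autosomal arms, 2L, 2R, 3L and 3R, since H4K16 acetylation is the modification made by MOF, the acetyltransferase of the dosage compensation complex that binds the X chromosome of male flies. The sex of the larvae is not given in the sources used here. Each arm was cut into 1 Mb windows, windows shorter than a share of 0.5 of that size were left out, and 22 X windows were compared with 97 autosomal windows by a two-sided permutation test with 100000 resamples, whose smallest p is 1e-05. The same test was applied to the windows' median log2 region length and median score. Windows are stretches of the same libraries, so these tests measure the spread along chromosomes and not between animals. X and autosomes were compared within each replicate, and an exact two-sided sign-change test over the 2 replicates could not go below p = 0.5. Values are given as the mean and SD of the 2 replicates, and the combined list stands beside them as the authors' pooled value. Overlap between replicates was set against 1000 random circular shifts of one list within each arm, whose smallest p is 0.001.

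The tests were checked on simulated lists with autosomal region lengths and 3621 regions, with 999 permutations each. Of 100 lists with no X difference, 0 were called for coverage and 7 for length. Regions in these lists were placed at random, in numbers set by arm length, so coverage was nearly equal by construction. These counts therefore do not give the rate of false calls in the real lists, whose regions need not be spread at random. All 100 lists with a coverage difference of 5.05 percentage points were called, with a mean estimate of 5.05. Random placement and autosomal lengths on X apply here too, so this does not give the rate of detection in the real lists. In 10 simulated pairs the second list was a random 50% of the first, and 49.99% of the first list was counted as overlapped. This checks only the counting, since the construction set the answer. In 10 pairs of unrelated simulated lists the overlap was 17.16%, against 17.20% after circular shifts. The tests, windows and alternatives were fixed before the data were examined, except for the split at a region length of 10 kb, the 5 length classes of the score, the restrictions of the combined list, the list of uncovered stretches, the end of X outside the windows, and the tests of the closing section on the log base, on XHet, on regions near or away from regions of at least 10 kb and on the distance of extra regions, which were chosen after the data had been examined. Regions are named by a rule fixed beforehand: the 5 X and 5 autosomal regions with the highest score in the combined list among those overlapped by at least 1 bp in both replicates, and the 3 longest of each group.

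Gene-based results were planned with 20 gene lists, on the condition that an annotation of the files' build was at hand. The gene table used here is of Release 6 of the genome, so no region was assigned to a gene, and the shares of marked genes, gene body coverage and gene lists were not analysed here. Exon and promoter positions were not analysed for the same reason. Region lists of the input libraries were not analysed here. Calculations were done in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.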

Results

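H4K16ac, a histone modification of open and transcribed chromatin, was profiled by ChIP-seq in wild-type Drosophila larvae of the third instar, in 2 ChIP replicates alongside 2 input DNA libraries. Replicate 1 gave 4070 enriched regions with a total length of 19769806 bp, and replicate 2 gave 4164 regions with a total length of 19738887 bp. The authors' combined list held 5252 regions and 24929238 bp. On the 5 large chromosome arms lay 3943 regions of replicate 1, 4038 of replicate 2 and 5067 of the combined list. All positions are FlyBase r5 coordinates. The read depth of the libraries is unknown, since the files give regions and scores and no read counts.

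The first comparison asked how H4K16ac-enriched regions were divided between X and the autosomes. X was covered over 48.2% ± 0.218 of its length (SD, n = 2), against 8.84% ± 0.083 (SD, n = 2) of the large autosomal arms, a ratio of 5.45 ± 0.076 (SD, n = 2). X makes up 18.8% of the length of the 5 large arms and held 55.9% ± 0.342 (SD, n = 2) of their covered bases. Among the autosomal arms, 2R was the most covered at 10.5% ± 0.075 (SD, n = 2). Arm 3R followed at 9.14% ± 0.078 (SD, n = 2). Arms 2L and 3L were covered over 7.92% ± 0.155 and 7.90% ± 0.027 (SD, n = 2). Chromosome 4, the small autosome, was covered over 9.20% ± 0.037 (SD, n = 2), which lies within the range of the large autosomal arms. In the authors' combined list the covered share was 60.3% on X and 11.2% on the large autosomal arms.

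**Figure D1:**
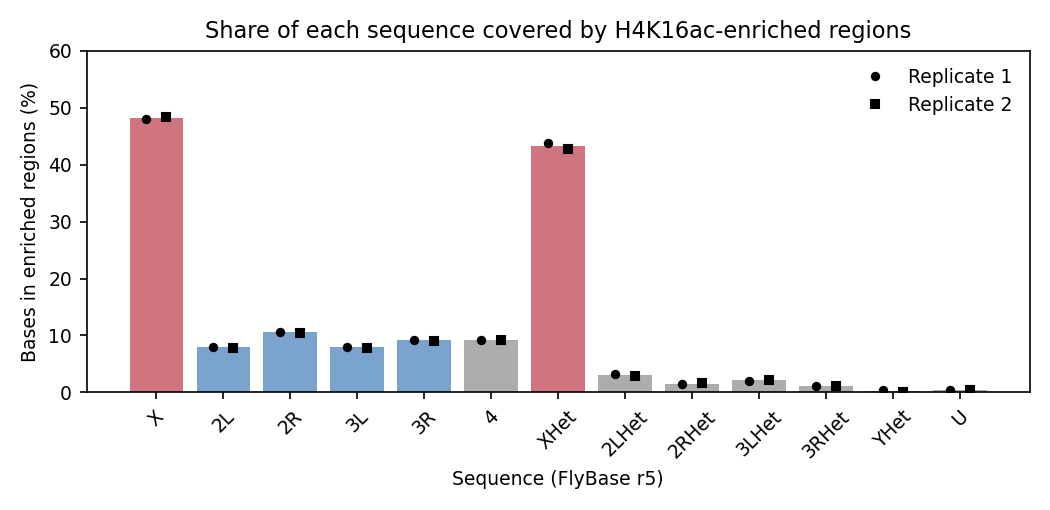
Percentage of bases in enriched regions for each sequence of FlyBase r5, with bars for the mean of the 2 ChIP replicates and points for each replicate (X sequences in red, large autosomal arms in blue, others in grey). X, at 48.2%, and XHet, at 43.2%, stand above the autosomal arms, which lie between 7.90% and 10.5%.

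The X and autosomal shares differed by far more than the replicates did. Averaged over 1 Mb windows, coverage was 49.0% on X (SD 14.02 across 22 windows) and 8.83% on the autosomes (SD 3.56 across 97 windows), a difference of 40.1 percentage points (two-sided permutation test over windows, p = 1e-05, the smallest it can give). The same test on single lists gave differences of 39.9 points in replicate 1, 40.3 points in replicate 2 and 50.0 points in the combined list. An exact permutation over the 5 large arms gave p = 0.2, which is the smallest p that 5 arms allow.

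In the mean of the replicates, all 22 X windows were covered more than the highest of the 97 autosomal windows. The windows leave out the end of X from 22000001 to 22422827, where coverage was 9.38% ± 0.785 (SD, n = 2), close to the autosomal mean. The most covered X window, from 11000001 to 12000000, had 75.5% ± 1.50 (SD, n = 2) of its bases in enriched regions, and the window from 19000001 to 20000000 had 68.8% ± 0.823 (SD, n = 2). The least covered X windows were those from 18000001 to 19000000, at 29.4% ± 0.055 (SD, n = 2), and from 3000001 to 4000000, at 29.7% ± 0.576 (SD, n = 2). On the autosomes the highest window lay on 2R from 19000001 to 20000000, at 19.8% ± 0.561 (SD, n = 2). The lowest lay on 2L from 14000001 to 15000000, at 1.08% ± 0.167 (SD, n = 2).

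**Figure D2:**
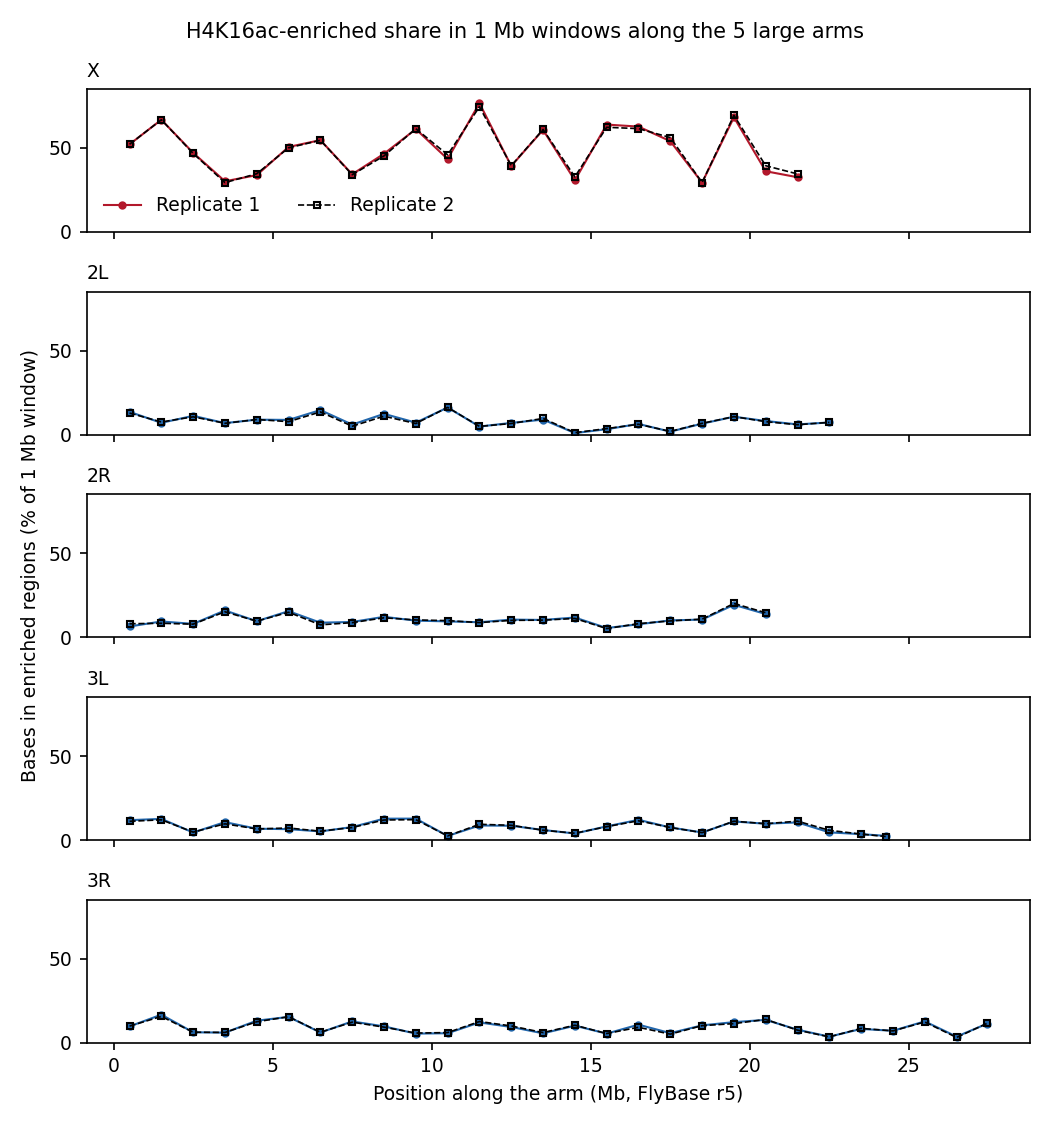
Percentage of bases in enriched regions in 1 Mb windows along each large arm, for replicate 1 (filled circles) and replicate 2 (open squares), with position in Mb on FlyBase r5. By the mean of the 2 replicates, X windows lie between 29.4% and 75.5%, and the highest autosomal window, on 2R, reaches 19.8%.

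Long stretches with no enriched region were rarer per Mb on X than on the large autosomal arms. Stretches of at least 100 kb with no base in a region of any of the 3 lists numbered 11 on X and 222 on the large autosomal arms, or 0.491 and 2.30 per Mb. The longest on X ran from 21503251 to 21828203, over 325.0 kb, and the next from 7239825 to 7541421, over 301.6 kb. On the autosomes the longest was on 2L from 14363433 to 15004951, over 641.5 kb, followed by 2R from 15559382 to 16131397, over 572.0 kb. These stretches were chosen after their values were seen and were not tested.

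A further comparison asked whether X held more regions, longer regions or both. Regions on X were on average 3.57 ± 0.134 times as long as autosomal ones (SD, n = 2) and 1.53 ± 0.079 times as dense per Mb (SD, n = 2). Mean region length was 10367 ± 522 bp on X and 2900 ± 36.9 bp on the autosomes (SD, n = 2). On X, 50% of the covered bases lay in regions of at least 34965 ± 80.6 bp (SD, n = 2), whereas on the autosomes they lay in regions of at least 3058 ± 44.5 bp (SD, n = 2).

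Regions of at least 10 kb lay mostly on X. Replicate 1 had 234 of them on X and 12 on the large autosomal arms, and replicate 2 had 224 and 9. In the combined list there were 223 on X and 41 on the autosomes, the latter holding 4.78% of autosomal covered bases. In the replicates such regions held 78.0% ± 1.28 (SD, n = 2) of the covered bases of X and 1.60% ± 0.168 (SD, n = 2) of those of the autosomes. Counting only regions of at least 10 kb, window coverage was 38.2% on X and 0.142% on the autosomes, a difference of 38.1 points (two-sided permutation test over windows, p = 1e-05). Counting only shorter regions, it was 10.7% on X and 8.68% on the autosomes, a difference of 2.04 points (permutation p = 0.0130). For the shorter regions the single replicates gave 1.53 points (p = 0.0666, permutation) and 2.54 points (p = 0.0020, permutation), so that this smaller difference did not pass in replicate 1 alone. These shares are of whole windows, and regions of at least 10 kb already took up 38.2% of X windows. Less sequence was thus left for shorter regions on X, and their share of that remaining sequence was not compared.

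**Figure D3:**
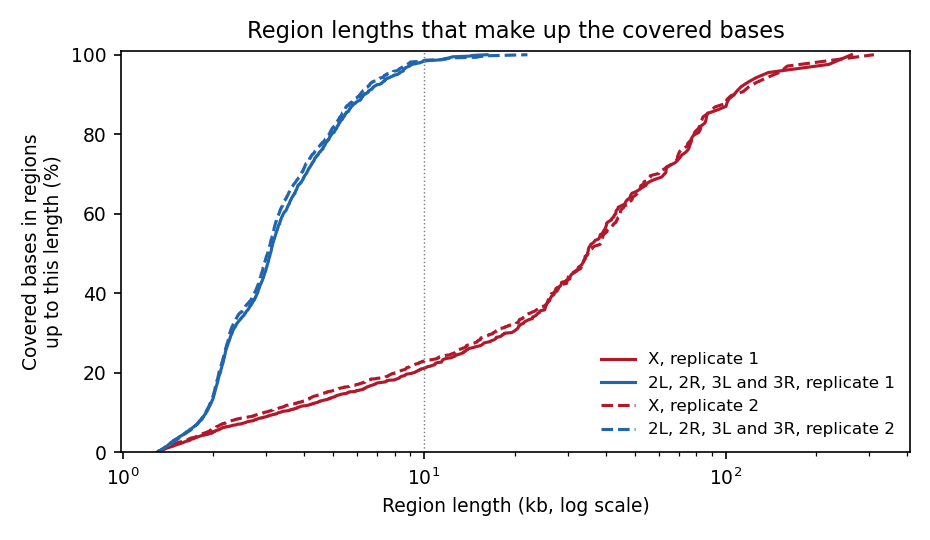
Cumulative percentage of covered bases (vertical axis) in regions up to a given length (horizontal axis, kb, log scale) for X in red and the large autosomal arms in blue, replicate 1 solid and replicate 2 dashed. On X 50% of the bases lie in regions of at least 34965 bp, against at least 3058 bp on the autosomes, and the dotted line marks 10 kb.

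The windows' median region length was 2730 bp on X and 2452 bp on the autosomes, a ratio of 1.11 or 0.16 on the log2 scale (two-sided permutation test over windows, p = 0.0010). In the combined list this contrast turned, with 2055 bp on X and 2467 bp on the autosomes (difference of -0.26 on the log2 scale, permutation p = 1e-05). The log2 difference was 0.21 in replicate 1 and 0.10 in replicate 2, 0.24 without the 2 windows at each arm end, 0.53 with regions under 1 kb apart merged, 0.62 among regions overlapped in the other replicate and 1.19 among the higher-scoring regions from the median of each list upward. Choosing by overlap or by score favours long regions, so the values of 0.62 and 1.19 may partly come from that choice. The combined list reaches down to 1001 bp, and without regions shorter than 1301 bp its difference was 0.12 (permutation p = 0.0111).

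The longest region of the combined list lay on X from 15589406 to 15902864, over 313.5 kb, with a score of 1.75. Replicates 1 and 2 covered 99.4% and 99.7% of it, in 3 and 2 regions. The X region from 19436114 to 19658882 spanned 222.8 kb with a score of 1.92, and 99.3% ± 0.703 (SD, n = 2) of it was covered in the replicates. The X region from 8963080 to 9177950 spanned 214.9 kb with a score of 1.74, and the replicates split it into 7 and 8 regions. The longest autosomal regions were far shorter. The one on 2L from 4958818 to 4982954 spanned 24.1 kb with a score of 1.17. On 3L a region from 16570238 to 16592670 spanned 22.4 kb with a score of 1.14, and on 2R a region from 19843522 to 19861310 spanned 17.8 kb with a score of 1.05.

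**Figure D4:**
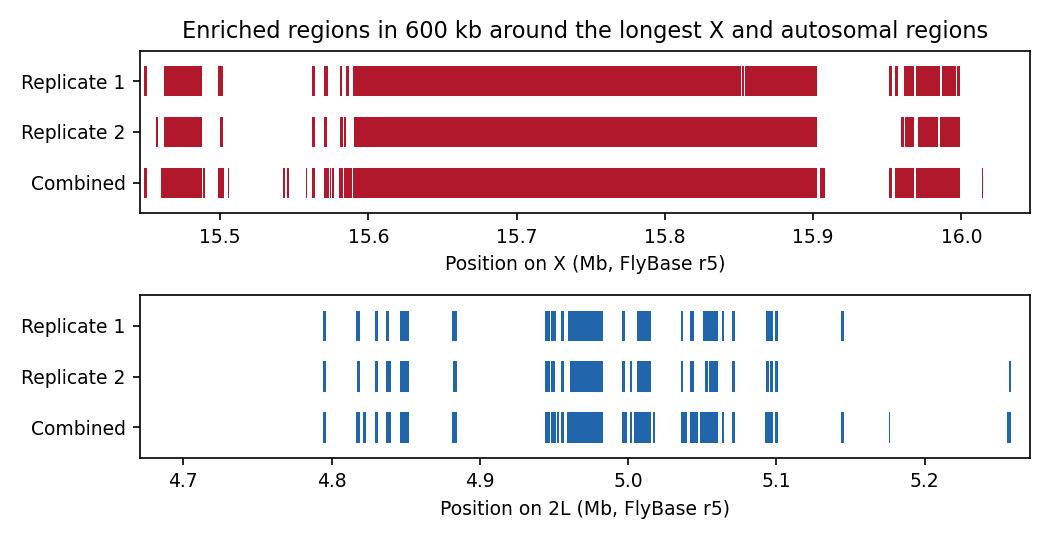
Enriched regions of replicate 1, replicate 2 and the combined list in 600 kb around the longest X region (top, red) and the longest autosomal region, on 2L (bottom, blue), with position in Mb on FlyBase r5. The X region of 313.5 kb is almost continuous in every list, while the regions on 2L around the one of 24.1 kb are separate and short.

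Scores, taken as log2 values, were next compared between X and the autosomes within each list. The windows' median score was 0.78 on X and 0.73 on the autosomes, a difference of 0.04 (two-sided permutation test over windows, p = 0.0230). In replicate 1 alone it was 0.04 (permutation p = 0.0548), which did not pass, and in the combined list it was -0.06 (permutation p = 0.0065), the opposite direction. It was 0.07 among the higher-scoring regions from the median of each list upward and 0.08 among regions overlapped in the other replicate. The first choice uses the score itself, and overlapped regions may score higher, so neither value is separate support. The contrast depended on region length. Among regions of at least 10 kb the median score was 1.58 ± 0.056 on X and 1.12 ± 0.030 on the autosomes (SD, n = 2), a ratio of 1.38. Over 22 X and 15 autosomal windows this difference was 0.46 (permutation test, Benjamini-Hochberg adjusted over the 5 classes, p = 1.667e-05). It came from 458 X regions and 21 autosomal regions in the 2 replicates together. This class was not matched for length. Autosomal regions reached at most 16187 and 22021 bp in replicates 1 and 2, against 261657 and 310398 bp on X. Median scores rose with length class in both groups, so an effect of length within this class cannot be told apart. Regions under 2 kb also scored higher on X, at 0.65 ± 0.012 against 0.46 ± 0.0013 (SD, n = 2; permutation, adjusted p = 1.667e-05).

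Between these lengths the X regions did not score higher. At 3 to 5 kb the median was 0.80 ± 0.036 on X and 0.92 ± 0.028 on the autosomes (SD, n = 2), and the window difference was -0.13 (permutation, adjusted p = 1.667e-05). At 5 to 10 kb the medians were 0.98 ± 0.0042 and 1.04 ± 0.00096 (SD, n = 2; permutation, adjusted p = 0.0615), which did not pass after adjustment. At 2 to 3 kb they were 0.74 ± 0.017 and 0.74 ± 0.011 (SD, n = 2; permutation, adjusted p = 0.811). In the combined list the difference at 2 to 3 kb was -0.09 (permutation, adjusted p = 1e-05) and that at 5 to 10 kb was -0.27 (permutation, adjusted p = 1e-05).

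**Figure D5:**
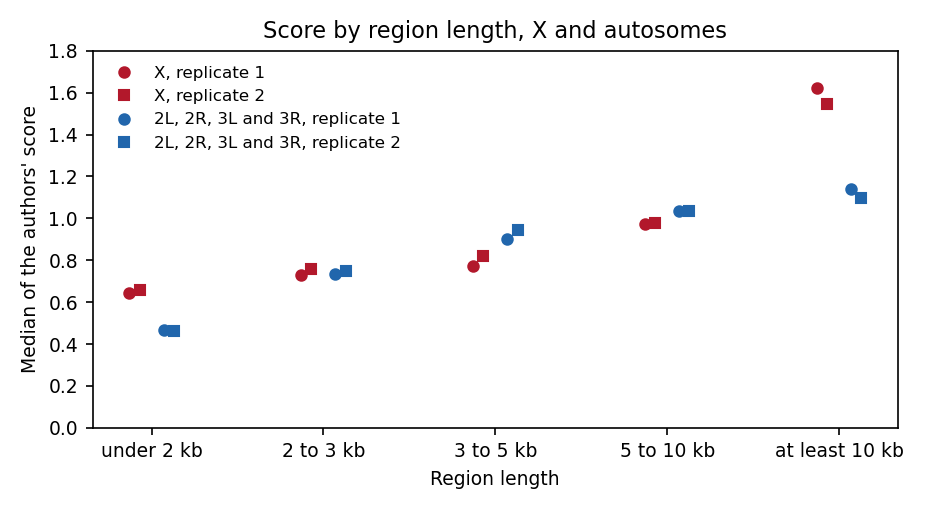
Median of the authors' score (vertical axis, read as log2) by region length class for X in red and the large autosomal arms in blue, with circles for replicate 1 and squares for replicate 2. X lies above the autosomes under 2 kb (0.65 against 0.46) and from 10 kb (1.58 against 1.12), and below them at 3 to 5 kb (0.80 against 0.92).

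Of the combined-list regions overlapped in both replicates, the one with the highest score lay on X from 1732852 to 1825624, over 92.8 kb. Its score was 2.12, and the highest-scoring overlapping regions of the replicates averaged 2.19 ± 0.174 (SD, n = 2). The next on X were 21468710 to 21503250 with a score of 2.07, 15460376 to 15488110 with 1.99, 10996348 to 11079052 with 1.97 and 10983274 to 10990910 with 1.95. The first of these, of 34.5 kb, ends at the edge of the longest uncovered stretch of X. These 5 regions spanned 7.64 to 92.8 kb. The 5 autosomal regions chosen in the same way had lower scores and spanned 3.48 to 8.55 kb. They were 1.69 on 3R from 4475046 to 4480502, over 5.46 kb, and 1.67 on 3L from 1773584 to 1778888, over 5.305 kb. The other 3 were 3L from 1616208 to 1619904 with 1.66, 3R from 1456048 to 1464600 with 1.65 and 3R from 19597028 to 19600502 with 1.59.

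The last comparison asked how far the 2 ChIP replicates gave the same regions. On the large arms 89.6% of the regions of replicate 1 were overlapped by at least 1 bp in replicate 2, and 88.8% in the reverse direction. After random circular shifts of one list the mean of both directions was 27.5% and reached at most 32.6%, against 89.2% observed (permutation by 1000 shifts, p = 0.001, the smallest they can give). Of the bases covered in either replicate, 83.5% were covered in both, against a mean of 18.2% after shifting. All 246 regions of at least 10 kb in replicate 1 and all 233 in replicate 2 were overlapped in the other replicate. The 412 and 454 regions with no overlap had median lengths of 1602 and 1597 bp, and none was longer than 4393 bp. By a rule of 1 bp long regions are overlapped more readily whatever the cause. These counts and lengths therefore do not show that long regions were reproduced better than short ones.

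The share of regions overlapped was lower on X, at 78.9% ± 2.29 (SD over the 2 directions), than on the large autosomal arms, at 92.8% ± 0.240. Shifted lists gave 60.2% on X and 15.97% on the autosomes. By bases, 84.8% of those covered in either replicate were shared on X and 82.0% on the autosomes, against means of 31.7% and 4.69% after shifting. These differences between X and autosomes were not tested.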

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

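The test of XHet against other heterochromatic sequences was chosen after its result was seen. The sequences outside the large arms and chromosome 4 were used in no comparison fixed beforehand. Those with more than 3 enriched regions in each replicate are given because a signal appeared there and no input values were used here to set it against. Coverage was 43.2% ± 0.735 on XHet (SD, n = 2), the heterochromatic sequence assigned to X. It was 2.15% ± 0.119 on 3LHet, 1.55% ± 0.140 on 2RHet, 1.14% ± 0.102 on 3RHet and 0.395% ± 0.032 on U, the unplaced sequence (SD, n = 2 each).

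XHet is 204112 bp long, and its enriched regions ran from 1168 to 126915 in replicate 1 and from 1712 to 127476 in replicate 2. One explanation is that reads of repeats were placed on heterochromatic sequence at large. The highest share on any other such sequence was 3.25%, on 2LHet in replicate 1, so wide coverage was not found on heterochromatic sequence at large. That contrast had been seen before the test was chosen, so it is no separate test of this explanation. Another explanation is that a short sequence was filled by a single region. The longest region held 42103 of the 89306 covered bp in replicate 1 and 46588 of 87185 in replicate 2. Of the XHet sequence outside that region, 29.1% and 25.8% was still covered, so 1 region does not account for the whole share. Reads of X-derived repeats placed on XHet stay open and were not tested. No biological explanation was tested, since the samples form no groups that bear on it.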

How the results depend on the processing

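No paired analysis was possible because no input values were used here that could be paired with the ChIP samples by replicate number. The coverage difference between X and autosomes kept its direction and its permutation p = 1e-05 under all 15 settings fixed before the data were examined (37.0 to 50.0 percentage points), and the replicate overlap stayed above that of every shifted list under all 5 (78.2% to 92.8%). The median length difference kept its direction and passed under 13 of 14 such settings (0.10 to 1.19, log2 scale). The values of 0.62 among overlapped regions and 1.19 among higher-scoring ones may partly come from choices that favour long regions. The length difference was -0.26 in the combined list, and, in settings chosen after seeing the data, 0.12 without its regions under 1301 bp and 1.83 among its regions overlapped in both replicates, which leaves the cause open. The median score difference of 0.04 was fragile. It was 0.038 without replicate 2 (permutation p = 0.0548) and 0.046 without replicate 1 (permutation p = 0.0191). Without arm 3L it was 0.038 (permutation p = 0.05275), and the cause was not tested. It turned to -0.060 in the combined list, and the cause was not tested. Among that list's regions overlapped in both replicates, chosen after seeing the data, it was 0.174, against at most 0.049 over 100 random shifts of the replicates. Such a choice favours high-scoring regions, which shifts do not mimic, so the value does not explain the turn. In length classes chosen after seeing the data, it was -0.129 at 3 to 5 kb (permutation, adjusted p = 1.667e-05). It was below 0 without passing at 2 to 3 kb (-0.0032, permutation, adjusted p = 0.811) and at 5 to 10 kb (-0.068, permutation, adjusted p = 0.0615), and tests of the pattern left its cause open. The score kept direction and call under 10 of 13 settings fixed beforehand, replicate 2 alone included (0.043 to 0.083). These include the higher-scoring regions (0.072) and the regions overlapped in the other replicate (0.083). Such choices are or may be tied to the score, so they are no separate support. Settings of the gene-based results, and the replicate block, were not run, since the gene table is of another genome release and no input values were used here. Read depth is unknown from these files, so weak regions missing from 1 replicate cannot be separated from regions below its detection limit.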

Other observations

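Of the tests in this part, those on restricted parts of the combined list, those by length class and that of the log base were chosen after the results they bear on were seen. By count, regions of the combined list that neither replicate held made up a larger share on X than on the autosomes, a difference that was not tested. Of its 1451 X regions, 715 (49.3%) were overlapped in neither replicate, against 646 of 3616 (17.9%) on the large autosomal arms. These X regions had a median length of 1335 bp and a median score of 0.48, compared with 9797 bp and 0.84 for the 449 X regions overlapped in both replicates. The autosomal regions overlapped in neither replicate were also short and low-scoring, at 1247 bp and 0.37, against 3061 bp and 0.72 for those overlapped in both. Shares of covered bases were not compared. Counts also depend on joining, since some broad X regions of the combined list were split into several in the replicates. For the 715 X regions the median distance to the nearest X region of at least 10 kb was 18742 bp. It was 29988 bp after 1000 circular shifts along the X outside those regions (two-sided permutation p = 0.002997), and single shifts gave 18411 to 36892 bp. Shifts also move regions into uncovered parts of X. Nearness to broad regions thus cannot be told apart from gathering in the enriched parts of X. A hypothesis is that the extra regions may be weak enrichment around the broad X regions that the single replicates did not reach, which was not tested. No replicate region was shorter than 1301 bp, so extra regions below that length could not be listed there at their own length.

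X regions were shorter than autosomal ones by median in the combined list alone. Whether the lower minimum length of that list accounts for this stays open. Without regions under 1301 bp the X minus autosome difference was 0.125 on the log2 scale (permutation p = 0.0111), but removing short regions raises the median where they are more frequent, whatever the cause. Short X regions that the replicates do not both hold would account for it: among regions overlapped in both replicates the difference was 1.83 (permutation p = 1e-05). Part of that value comes from the choice itself, as long regions are overlapped more readily. It lies above the 0.97 that 100 random shifts of the replicates gave at most. Shifts do not mimic a choice that favours high-scoring regions, however, so the value does not settle whether such short regions account for the pattern. The tests do not separate these explanations, and no biological explanation was tested.

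The X regions of 3 to 5 kb scored lower than autosomal ones while X regions under 2 kb and of at least 10 kb scored higher. One scale factor for the whole X, as from a normalization that treats X differently, stays open. The lowest class difference was -0.129 (permutation, adjusted p = 1.667e-05), but the classes rest on called length, which signal strength itself can alter, so opposite signs do not exclude it. X regions of 3 to 10 kb within 5 kb of a region of at least 10 kb scored lower than those farther away by a mean difference of -0.032 (SD 0.028, n = 2; permutation p = 0.0472, not adjusted), with -0.052 in replicate 1 and -0.012 in replicate 2. The medians compared were not matched for length within 3 to 10 kb. X medians were 0.80 at 3 to 5 kb and 0.98 at 5 to 10 kb, so an effect of length cannot be told apart. In a test added once the difference of -0.032 was known, X regions of 3 to 5 kb farther than 5 kb from regions of at least 10 kb, 79 and 87 per replicate, still differed from autosomal ones by -0.118 (permutation p = 1e-05). Why the difference remains away from broad regions stays open, and no biological explanation was tested.

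In each list at least 99.98% of the deposited scores of regions under 10 kb matched log2 of a ratio of whole numbers times 1 constant, and at most 0.081% matched in base e or 10. In the combined list the 10 highest scores, from 2.24 to 3.54, were all in regions of 1001 to 1155 bp, and 0 of the 10 were overlapped in both replicates. No replicate region was shorter than 1301 bp, so none of these could be listed there at its own length. Some of them lay on U and 3LHet, others on the large arms. The highest score, on 2L from 5175688 to 5176698, corresponded to 8 times the ratio of the most common score. The next ones, on U and then on 3LHet and X, were 7 and 5 times that ratio.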
